A study of Mus musculus with 11 samples.

How the data were processed

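RNA-seq data from 11 libraries of mouse omental tumors, in 5 groups by the inoculated cell line, were taken from 1 deposited table of raw whole-number read counts per Ensembl gene, which the authors made with STAR 2.7.1a and featureCounts 1.6.2 on the GRCm38 (mm10) build. Per the labels, tumors were flash frozen, RNA was extracted with phenol and polyA RNA was selected. The protocol names both an Illumina TruSeq RNA kit and a stranded KAPA mRNA HyperPrep kit and does not say which library had which. The annotation release and the strand setting of the counting are not given in the sources used here. Counts were summed per gene as deposited, with no normalization by the authors.

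The table held 55573 gene rows, of which 22047 were 0 in all libraries. Gene symbols, biotypes and positions came from GENCODE release M21 on GRCm38. Of the identifiers 55480 matched, and the 93 others held at most 0.001% of the counts of any library. Total counts were 14596910 and 11311715 in BPPNM, 9840199 and 12092379 in PPNM, 6523006, 7042041 and 11644788 in KPCA, 9006733 and 9418831 in KPCA.C, and 10742632 and 8386871 in KPCA.FST.OE. A count of 0 over a group was read against a floor of 3 counts over the whole group, and the fold then given is a lower bound. For a group with 1 to 3 counts a ratio of depth-scaled counts is given with its 95% counting interval. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

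The planned fit held all 11 libraries as separate samples. A check of replicate pairs on genes with at least 20 summed counts found that the KPCA.FST.OE libraries differed by little more than counting noise, with a chi-square per gene of 1.56 against 42.35 to 98.8 in the other pairs. These libraries were therefore summed to 1 sample, after the data were seen and although the labels give them different days, and the planned fit is given as an alternative. Genes were filtered with filterByExpr on all 11 libraries, which kept 15838 and left out 39735. Counts were scaled by TMM factors and fitted with the quasi-likelihood model of edgeR 4.0.16 (glmQLFit, glmQLFTest, two-sided) in R 4.3.3, with 1 coefficient per group, 10 samples, 5 residual degrees of freedom and 4.72 prior degrees of freedom. The biological coefficient of variation was 0.379. The lone KPCA.FST.OE sample was assumed to vary like the other groups. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. CPM are scaled by the TMM factors unless stated otherwise, SD is over libraries, and SE is that of the log2 fold change.

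The comparisons, the named-gene rule and 37 gene lists of cell types and pathways suited to this tissue were fixed before the data were examined. Each list with at least 3 tested members was tested with camera of limma 3.58.1 on the same fit, with a preset inter-gene correlation of 0.01 and, as an alternative, a correlation estimated per list. This gave 35 tested lists, adjusted within a comparison. The list of engineered genes was read gene by gene, and the hepatocyte list had 0 tested members. Counts of members called are given over all tested genes and, as stated, adjusted over the list alone. Named genes were the engineered genes and, in each direction, the 10 called genes with the largest change that had at least 5 CPM in every library of the higher group and group ranges that did not overlap. Predicted genes, clone names and variable segments of immunoglobulins and T cell receptors were left out of that choice. From each list past its threshold, and always from the T cell, macrophage and activin lists, up to 4 called members with the smallest p were added, or the 2 members with the highest mean CPM where none was called. Each T cell and activin list result that is not in the report stands among the other observations.

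The fit was tested on simulated data with 15838 genes and 50 genes changed at each of 4 sizes. At 2-fold, 4-fold, 16-fold and 64-fold, the share of changed genes recovered was 2%, 54%, 90% and 100% in BPPNM versus PPNM. It was 2%, 48%, 94% and 100% in KPCA.C versus KPCA, 0%, 26%, 78% and 94% in KPCA.FST.OE versus KPCA, and 0%, 44%, 94% and 100% in KPCA versus PPNM. Of 15638 unchanged genes 3, 10, 4 and 6 were called. A simulated list of 25 changed genes was called in each comparison, and of 35 unchanged lists 0, 0, 0 and 1 were. The simulated genes varied independently, so this does not show how often unchanged lists of correlated genes would be called. In BPPNM versus PPNM the estimated correlation of the real lists ranged from -0.002 (p53 targets) to 0.944 (skeletal muscle).

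Alternatives planned before the data were examined were RLE factors, no filter on low counts, a fit of the compared groups only, the replicate number as a block, DESeq2 1.42.0 (Wald test, on the same 10 samples and not on the 11 libraries as planned), and each library left out in turn. Deviations of same-numbered libraries from their group means were correlated between -0.327 and 0.099 over the comparisons, so the number was not read as pairing samples. The summing of KPCA.FST.OE was chosen after the data were seen, so its planned form as 2 samples became an alternative only then, and nuclear protein-coding genes only and, for the correlation, separate KPCA libraries as controls (1 for one change and 2 for the other, in 6 ways) were added after the data were seen. KPCA.FST.OE versus PPNM was also run after the data were seen, as a comparison within a library set. The correlation of changes was set beside 20 simulations of unchanged groups that share the KPCA controls. Copies of genes were searched with BLAST 2.17.0 among the transcripts of the same annotation, and a copy had at least 90% identity over at least 50% of the longest transcript. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, tests and figures. No library or value column was left out. No group held 4 or more samples and no comparison had 3 samples on each side, so neither a test for outlying samples nor a count over other splits of the samples was made.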

Results

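Polyadenylated RNA was sequenced in 11 libraries from tumors that grew in the omentum, a fatty fold of the peritoneum, of C57BL/6 mice inoculated with engineered fallopian tube cells. Fallopian tube epithelium is regarded as a tissue of origin of high-grade serous ovarian carcinoma. Each line carried a mutant p53 allele. The BPPNM line (2 libraries, tumors taken on day 56) also lacked Brca1, Pten and Nf1 and overexpressed Myc. The PPNM line (2 libraries, day 53) carried the same changes with Brca1 left intact. The KPCA line (3 libraries, day 35) was clone B of cells with an activating mutant KRAS that overexpressed Ccne1 and Akt2. The KPCA.C line (2 libraries, day 21) was clone C with the same listed genotype. The KPCA.FST.OE line (2 libraries, days 44 and 45) was clone B with overexpression of FST, which encodes follistatin, a secreted inhibitor of activin. The day of harvest differed between all groups, so genotype and tumor age could not be separated in any comparison. Total counts per library ranged from 6523006 to 14596910.

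The first principal component of log2 CPM, the read count scaled to library size, held 33.9% of the variance and placed the BPPNM and PPNM libraries apart from KPCA. The next component held 24.6% and placed KPCA.C apart from the other groups. The KPCA.FST.OE libraries differed by little more than counting noise. The median variance between them was 1.26 times counting noise, and 8.8% of genes lay beyond the 95% counting interval. In the other pairs of replicates these values ranged from 4.55 to 29.63 times and from 37.7% to 70.6%. Their counts were therefore summed as 1 sample, a departure from the planned fit of 11 libraries that was chosen after the data were seen. The labels give these libraries different days of harvest, 44 and 45, and so separate animals, which a match this close does not bear out. Whether both were made from 1 RNA sample, with a wrong label on 1 of them, is open. For the other groups the labels do not say whether the replicates came from separate animals, so each p-value measures the spread between these samples. A further split did not follow genotype: 48 features had at least 10 counts in each of the 6 BPPNM, PPNM and KPCA.FST.OE libraries and at most 3 counts in each of the 5 KPCA and KPCA.C libraries. The opposite pattern was found in 0 features. Of the 48 features 8 were protein coding. The mitochondrial genes mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3 had 0 counts in all 5 libraries of the KPCA and KPCA.C set. The largest number in any other of the 10 groupings of 3 groups against 2 was 44, for PPNM, KPCA and KPCA.FST.OE against BPPNM and KPCA.C. The next largest was 12. BPPNM versus PPNM and KPCA.C versus KPCA lay within a set. KPCA.FST.OE versus KPCA and KPCA versus PPNM each compared 1 set with the other and gave no value within a set.

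**Figure D1:**
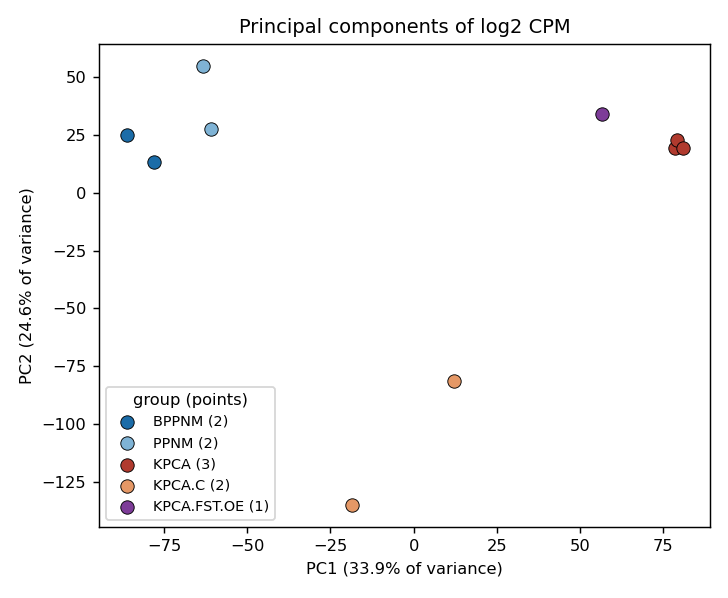
Principal components of log2 CPM over 15838 genes, with 1 point per sample (the 2 KPCA.FST.OE libraries were summed to 1 point). The horizontal axis is the first component (33.9% of variance) and the vertical axis the next one (24.6%); KPCA lies between 78.5 and 80.9 on the first component, and the KPCA.C tumors lie at -81.5 and -135.1 on the vertical axis.

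The engineered genes were read first, since the labels state which were overexpressed or lost. Akt2 (ENSMUSG00000004056, chromosome 7, 27591552 to 27640826), a serine-threonine kinase of the PI3K pathway, reached 246 CPM ± 41.4 (SD, n = 3) in KPCA against 81.6 ± 4.76 (SD, n = 2) in PPNM, a log2 fold change of 1.59 (SE 0.28, edgeR adjusted p = 0.0123). In KPCA.C it reached 1270 CPM ± 30.5 (SD, n = 2), a log2 fold change of 2.37 over KPCA (SE 0.26, edgeR adjusted p = 0.00241). Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), which encodes p53, was also higher in KPCA.C, at 145 CPM ± 21.4 (SD, n = 2) against 23 ± 4.2 (SD, n = 3) in KPCA, a log2 fold change of 2.65 (SE 0.29, edgeR adjusted p = 0.00241). Kras (ENSMUSG00000030265) was 1.32 higher on the log2 scale in KPCA.C than in KPCA (SE 0.31, edgeR adjusted p = 0.03). The Kras call was lost without KPCA replicates 1, 2 or 3 (edgeR adjusted p = 0.0624, 0.114 and 0.0842) and without KPCA.C replicate 2 (0.149). Akt2 and Trp53 stayed called in KPCA.C versus KPCA without any 1 of the 5 libraries. The Akt2 call in KPCA versus PPNM was lost without PPNM replicates 1 or 2 (edgeR adjusted p = 0.0865 and 0.0503).

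Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374), a growth-promoting transcription factor, stood at 411 CPM ± 173 (SD, n = 2) in BPPNM and 264 ± 164 (SD, n = 2) in PPNM, against 89.7 ± 13.6 (SD, n = 3) in KPCA. It was 1.55 lower on the log2 scale in KPCA than in PPNM (-1.55, SE 0.43, edgeR adjusted p = 0.048). This call was lost without any 1 of the 5 libraries: the edgeR adjusted p was 0.121, 0.151 and 0.098 without KPCA replicates 1, 2 and 3, and 0.052 and 0.328 without PPNM replicates 1 and 2. The Myc log2 fold change itself was -2.079 without PPNM replicate 1 and -0.718 without PPNM replicate 2. Ccne1, which encodes cyclin E1, had 25.5 CPM ± 8.46 (SD, n = 3) in KPCA and 10.2 ± 2.96 (SD, n = 2) in PPNM, which did not pass (log2 1.31, SE 0.52, edgeR adjusted p = 0.133). Fst (ENSMUSG00000021765, chromosome 13, 114452290 to 114458951) had 29.5 CPM in the summed KPCA.FST.OE sample and 35.9 ± 4.07 (SD, n = 3) in KPCA, a log2 fold change of -0.27 (SE 0.58, edgeR adjusted p = 0.887). The labels do not give the species of the FST sequence, and reads from a sequence that differs from the mouse gene need not be counted there. Brca1 had 23.2 CPM ± 0.552 (SD, n = 2) in BPPNM and 18.4 ± 6.56 (SD, n = 2) in PPNM (log2 0.33, edgeR adjusted p = 0.976). Counts over a whole gene do not show whether it was edited, and the tumors also held host cells, so the Brca1, Pten and Nf1 counts do not check the loss of these genes.

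**Figure D2:**
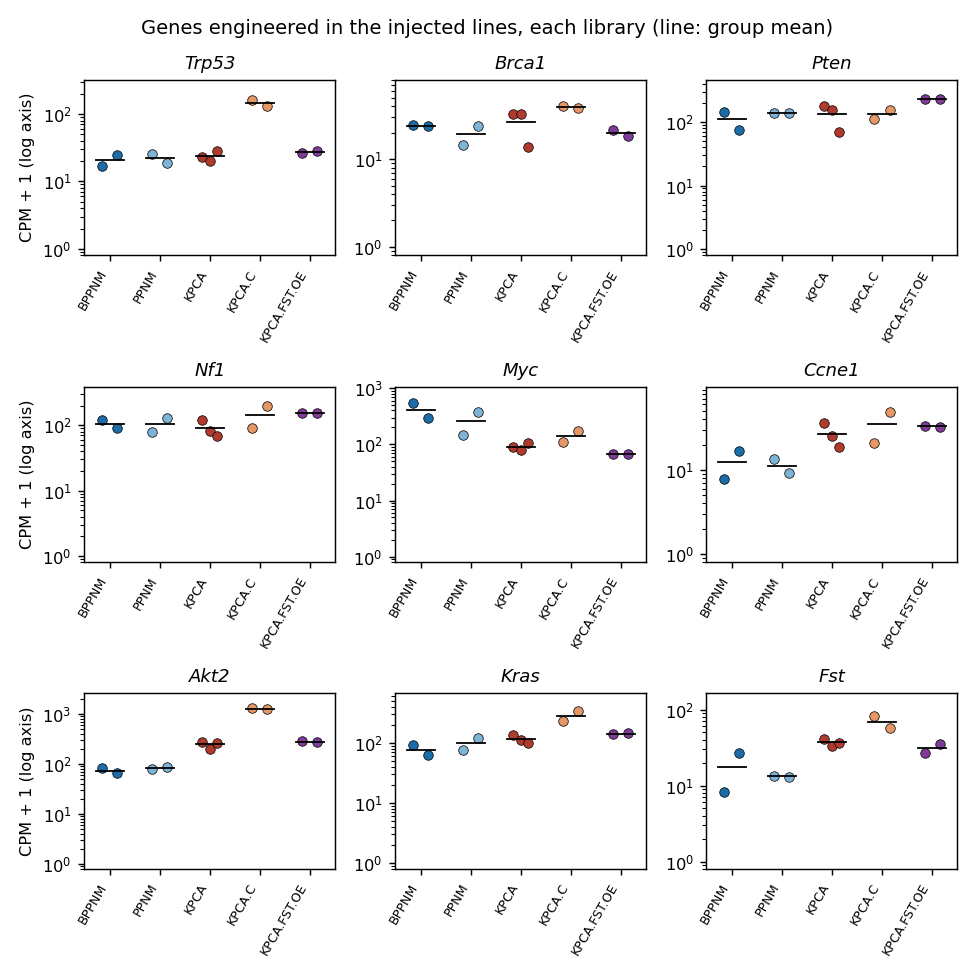
CPM plus 1, on a log axis, of the 9 engineered genes in each library, grouped by line, with points for libraries and a line at the group mean. Akt2 and Trp53 stand apart in KPCA.C (group means 1270 and 145 CPM), and Fst is at 29.5 CPM in KPCA.FST.OE against 35.9 CPM in KPCA.

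BPPNM versus PPNM asked how tumors that also lacked Brca1, a gene of homologous recombination repair, differed from tumors that kept it. Epithelial genes were lower in BPPNM: 7 of the 16 tested members of the epithelial and fallopian tube list fell, with a median log2 fold change of -3.55. Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129), an epithelial adhesion molecule, had 0.849 CPM ± 0.608 (SD, n = 2) in BPPNM and 73.2 ± 52.6 (SD, n = 2) in PPNM, a log2 fold change of -6.45 (SE 0.75, edgeR adjusted p = 0.01). Esrp1 (ENSMUSG00000040728, chromosome 4, 11331933 to 11386783), an epithelial splicing regulator, had 0 counts in BPPNM and 297 in PPNM and was at least 117-fold lower. The tight junction gene Cldn7 (log2 -6.41, edgeR adjusted p = 0.0142) and the epithelial transcription factor gene Elf3 (log2 -4.51, edgeR adjusted p = 0.0302) fell too. The Epcam call was lost without BPPNM replicates 1 or 2 (edgeR adjusted p = 0.0803 and 0.0787), and the Esrp1 call also without PPNM replicate 1 (0.0502). The Cldn7 and Elf3 calls were lost without BPPNM replicates 1 or 2 or PPNM replicate 1 (edgeR adjusted p between 0.0642 and 0.167).

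Among the lower genes with the largest changes, Muc4 (ENSMUSG00000079620, chromosome 16, 32735886 to 32782391), a membrane mucin gene, had 3 counts in BPPNM and 661 in PPNM, a ratio of 260 (95% counting interval 88.7 to 1270, edgeR adjusted p = 0.000236). The gel-forming mucin gene Muc5b had 1 count against 946, a ratio of 1120 (95% counting interval 200 to 44200). Ratios were 485 for the claudin gene Cldn3 (95% counting interval 86.7 to 19200), 363 for the immunoglobulin transporter gene Pigr (64.6 to 14400) and 234 for Fcgbp (64.5 to 1940). Tspan1, Fut2, Atp10b and Grb7 had 0 counts in BPPNM and were at least 101-fold, 78.4-fold, 78.0-fold and 66.1-fold lower. Each of these intervals and bounds covers counting error only. The higher genes with the largest changes included Gas1 (log2 4.61), the transcription factor gene Tbx3 (4.56), the opioid precursor gene Penk (4.25) and Ndufa4l2 (4.10). The prostaglandin receptor gene Ptgfr (log2 3.09), the adenylate cyclase gene Adcy3 (2.94), Plac8 (2.76), Rcn1 (2.5), Syce2 (2.5) and Nrn1 (2.16) followed. The edgeR adjusted p of these 10 genes lay between 0.0145 and 0.0404. Rcn1, which encodes a calcium-binding protein of the endoplasmic reticulum, had 201 CPM ± 0.241 (SD, n = 2) in BPPNM against 35.6 ± 0.364 (SD, n = 2) in PPNM. Except for Muc4, each gene named here lost its call without BPPNM replicates 1 or 2, and all but Pigr and Tspan1 also without PPNM replicate 1. Gas1, Tbx3, Penk, Ndufa4l2, Ptgfr, Rcn1 and Syce2 lost it without PPNM replicate 2 as well. The edgeR adjusted p in these fits lay between 0.0502 and 0.36.

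In the test by edgeR 96 of 15838 genes passed at an adjusted p of 0.05, 12 higher and 84 lower in BPPNM. An unadjusted p under 0.05 was found for 1505 genes, and DESeq2 called 529. The direction was less one-sided in other fits, with 197 higher and 332 lower by DESeq2, 442 and 552 by edgeR without a filter on low counts, and 37 and 74 without PPNM replicate 2. Of the 35 lists tested by camera, the set test of limma, 13 passed with a preset correlation of 0.01 and 0 with an estimated correlation. The epithelial list had a camera adjusted p of 7.51e-29 (adjusted p = 0.138 with an estimated correlation), and 12 of its members fell when adjusted over the list alone. The T cell list was higher as a whole (median log2 1.77, camera adjusted p = 4.09e-06; adjusted p = 0.59 with an estimated correlation), but edgeR called 0 of its 18 members, over all genes or over the list alone. Of these members 5 had an unadjusted p under 0.05, and DESeq2 called 0. Without BPPNM replicate 2 the T cell median was 0.953 (limma camera adjusted p = 0.0087). Cd8a, a cytotoxic T cell co-receptor gene, had 1.9 CPM ± 1.41 (SD, n = 2) against 0.307 ± 0.148 (SD, n = 2), with an edgeR adjusted p of 0.41. Lck, a T cell kinase gene, had a log2 fold change of 2.05 (edgeR adjusted p = 0.197). The cytotoxic and NK cell list was higher by a median of 2.25, or 1.83 with genes at 0 to 3 counts at their bound (camera adjusted p = 4.9e-06; adjusted p = 0.542 with an estimated correlation). Of its 14 members 0 were called by edgeR or DESeq2, and 6 had an unadjusted p under 0.05. The matrix remodelling list was lower by a median of -1.06 (camera adjusted p = 0.000152; adjusted p = 0.138 with an estimated correlation). Of its 14 members 1 fell, the collagenase gene Mmp13 (log2 -3.54, SE 0.52, edgeR adjusted p = 0.022), and 7 fell when adjusted over the list alone. The Mmp13 call was lost without BPPNM replicates 1 or 2 or PPNM replicate 1 (edgeR adjusted p = 0.167, 0.177 and 0.108). The homologous recombination repair list, chosen for the Brca1 loss, had a median of 0.14 (limma camera adjusted p = 0.499). Of its 19 members 0 passed by edgeR, by DESeq2 or at an unadjusted p under 0.05. The cytosolic DNA sensing list had a median of 0.23 (limma camera adjusted p = 0.0702), with 0 of 8 members called by edgeR or DESeq2 and 2 at an unadjusted p under 0.05.

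The other lists past the threshold in BPPNM versus PPNM each lost their call without 1 or more of the libraries. The plasma cell (median 2.27, limma camera adjusted p = 0.00181), macrophage and monocyte (0.43, 0.0114), interferon response (0.65, or 0.63 with genes at 0 to 3 counts at their bound, 0.00181) and MHC class I presentation (0.81, 0.00181) lists were higher. In each edgeR called 0 members, and 4, 0, 2 and 3 members had an unadjusted p under 0.05 and 1, 0, 1 and 0 passed by DESeq2. Their adjusted p values with an estimated correlation were 0.669, 0.725, 0.753 and 0.725. Without BPPNM replicate 2 the plasma cell, interferon and MHC class I medians were 0.519, 0.147 and 0.465, and without PPNM replicate 2 the macrophage median was 0.062. Without PPNM replicate 1 the plasma cell, macrophage and interferon medians were 5.376, 0.804 and 1.217. Without PPNM replicate 2 the camera adjusted p values of these lists were 0.17, 0.336, 0.223 and 0.0941, and without BPPNM replicate 2 those of the first 3 were 0.191, 0.0578 and 0.43. The hypoxia and glycolysis (-0.78, 0.000256), inflammatory cytokine (-0.77, 0.0135) and replication-dependent histone (-1.22, 0.0178) lists were lower, with adjusted p = 0.653 with an estimated correlation in each. In these 3 lists edgeR called 0 of 16, 19 and 4 members, 2, 6 and 1 had an unadjusted p under 0.05, and DESeq2 called 0, 3 and 0. Over the list alone 1 cytokine gene rose and 2 fell, and no hypoxia or histone gene passed. The limma camera adjusted p was 0.0664 for hypoxia without BPPNM replicate 2, with a median of -0.44. It was 0.0595 and 0.302 for the cytokines without BPPNM replicate 1 and PPNM replicate 1, with a median of -0.352 in the latter fit, and 0.0578 and 0.211 for the histones without BPPNM replicate 2 and PPNM replicate 2. The epithelial, T cell, cytotoxic and matrix lists passed without any 1 of the 4 libraries. Single genes were less firm: without BPPNM replicates 1 or 2 or PPNM replicates 1 or 2 in turn, edgeR called 4, 3, 9 and 111 genes, and Muc4 was the 1 of 24 named called genes that stayed called in all 4 fits.

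**Figure D3:**
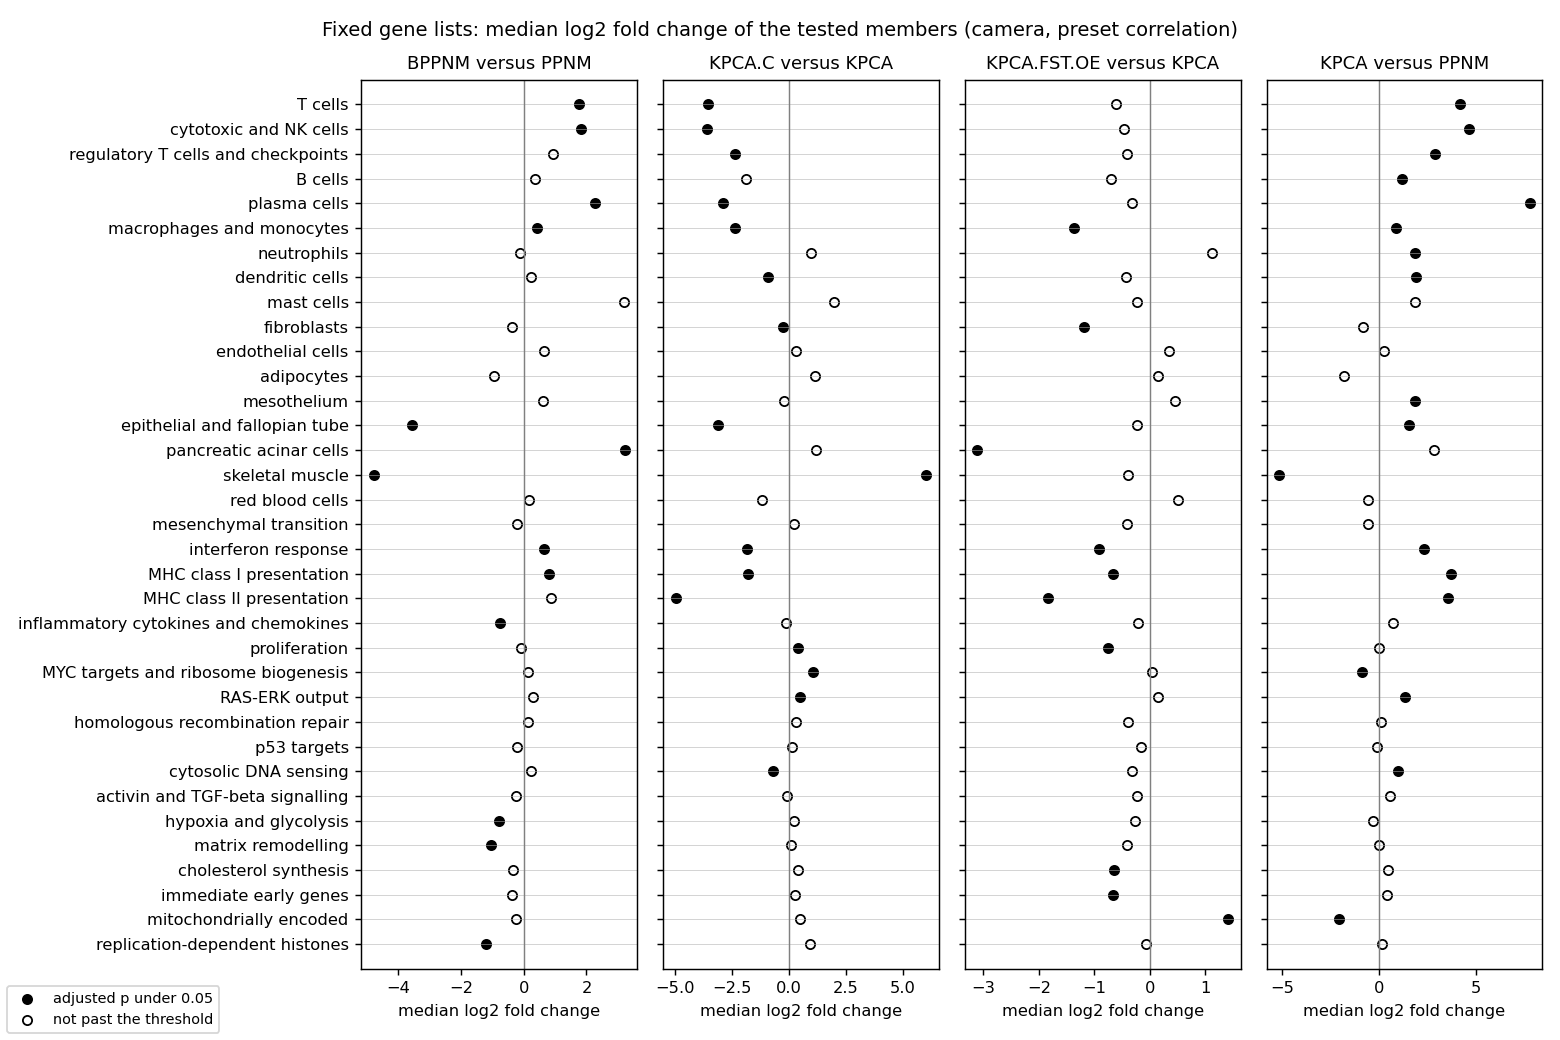
Median log2 fold change of the tested members of 35 gene lists in the 4 comparisons, 1 panel each, with genes at 0 to 3 counts in a group set to their bound. Filled points have a camera adjusted p under 0.05 with a preset correlation of 0.01 (13, 16, 10 and 18 lists from left to right); with an estimated correlation 0 lists passed in any panel.

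KPCA.C versus KPCA asked how tumors from clones with the same listed genotype differed, 21 and 35 days after inoculation. Several immune lists were lower in KPCA.C: 11 of 18 T cell genes, 11 of 19 macrophage and monocyte genes and all 7 MHC class II presentation genes fell. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) had 1.03 CPM ± 1.28 (SD, n = 2) in KPCA.C and 20.5 ± 3.49 (SD, n = 3) in KPCA, a log2 fold change of -4.30 (SE 0.9, edgeR adjusted p = 0.0201). Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), the macrophage growth factor receptor, had 50.2 CPM ± 13.6 (SD, n = 2) against 289 ± 6.77 (SD, n = 3), a log2 fold change of -2.52 (SE 0.28, edgeR adjusted p = 0.00241). H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674), which presents antigen to helper T cells, had 18.4 CPM ± 10.3 (SD, n = 2) against 706 ± 100 (SD, n = 3), a log2 fold change of -5.26 (SE 0.74, edgeR adjusted p = 0.00454). Epithelial genes fell as well, with Epcam at 1.27 CPM ± 0.435 (SD, n = 2) against 273 ± 100 (SD, n = 3), a log2 fold change of -7.74 (SE 0.77, edgeR adjusted p = 0.00241). Of these 4 genes Cd8a lost its call without KPCA replicates 2 or 3 (edgeR adjusted p = 0.0607 and 0.0562).

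Within the immune lists, the T cell kinase gene Lck fell (log2 -3.05, edgeR adjusted p = 0.00901), as did the co-receptor gene Cd8b1 (log2 -4.82, edgeR adjusted p = 0.0171), and Itk had 1 count against 102, a ratio of 68.1 (95% counting interval 11.9 to 2720). Over the list alone 16 T cell genes fell and 1 rose, and the median was -3.71, or -3.57 with genes at 0 to 3 counts at their bound (camera adjusted p = 1.31e-11; adjusted p = 0.187 with an estimated correlation). Of the 14 cytotoxic and NK cell genes 9 fell, 12 over the list alone, with a median of -3.95, or -3.59 at the bound (camera adjusted p = 3.26e-10; adjusted p = 0.187 with an estimated correlation). Ifng and Fasl had 0 counts in KPCA.C and were at least 15.1-fold and 11.1-fold lower, and the chemokine gene Ccl5 fell (log2 -3.53, edgeR adjusted p = 0.0211). Of 14 regulatory T cell and checkpoint genes 4 fell, 6 over the list alone (median -2.36, camera adjusted p = 2.9e-05; adjusted p = 0.255 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, had 8.26 CPM ± 3.55 (SD, n = 2) against 51.1 ± 3.42 (SD, n = 3) (edgeR adjusted p = 0.00371), and the inhibitory receptor gene Lag3 fell (log2 -2.45, edgeR adjusted p = 0.02). Macrophage genes had a median of -2.38, and 15 fell over the list alone (camera adjusted p = 7.05e-14; adjusted p = 0.187 with an estimated correlation). The Fc receptor gene Fcgr1 (log2 -3.83) and the monocyte chemokine receptor gene Ccr2 (log2 -5.16) were among them. Of 9 dendritic cell genes 3 fell (median -0.93, camera adjusted p = 0.00472; adjusted p = 0.268 with an estimated correlation). The transcription factor gene Irf8 had a log2 fold change of -2.73 (edgeR adjusted p = 0.00241), and Xcr1 had 0 counts and was at least 8.01-fold lower. The neutrophil list did not follow, with a median of 0.97 (limma camera adjusted p = 0.671). Of its 12 members 1 fell by edgeR, Csf3r (log2 -3.37, edgeR adjusted p = 0.00611), while 4 were higher and 2 lower at an unadjusted p under 0.05. The B cell list was at -1.9 (limma camera adjusted p = 0.0514), with 1 of 5 members down, Cd22 (log2 -2.41, edgeR adjusted p = 0.0176). Csf3r and Cd22 were named after their values were seen. Without KPCA.C replicate 1 the dendritic cell list had a camera adjusted p of 0.126, and without KPCA.C replicate 2 its median was -2.534. The cytotoxic and NK cell median was -7.462 without KPCA.C replicate 1 and -3.061 without KPCA.C replicate 2. Cd8b1 lost its call without KPCA.C replicate 2 (edgeR adjusted p = 0.0764). Ifng, Fasl, Ccl5, Lag3 and Xcr1 lost theirs without KPCA replicate 2 or KPCA.C replicate 2, and each also without 1 or more of the other libraries (edgeR adjusted p between 0.0506 and 0.113).

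Antigen presentation and interferon genes moved with them. The MHC class II list had a median of -4.98 (camera adjusted p = 5.5e-17; adjusted p = 0.187 with an estimated correlation), and Ciita, its master regulator, had 0.722 CPM ± 0.165 (SD, n = 2) against 44.3 ± 10.1 (SD, n = 3) (edgeR adjusted p = 0.00244). Of 26 interferon response genes 8 fell, 14 over the list alone (median -1.85, camera adjusted p = 4.29e-11; adjusted p = 0.378 with an estimated correlation). They included Gbp4, an interferon-induced GTPase gene (log2 -4.25, edgeR adjusted p = 0.00241), and Cxcl9, a T cell attracting chemokine gene (log2 -5.52, edgeR adjusted p = 0.0176). The interferon response median was -3.381 without KPCA.C replicate 1 and -1.196 without KPCA.C replicate 2. Of 14 MHC class I presentation genes 4 fell, 12 over the list alone (median -1.79, camera adjusted p = 3.25e-09; adjusted p = 0.351 with an estimated correlation). The peptide transporter gene Tap2 had a log2 fold change of -2.24 and the regulator gene Nlrc5 one of -2.02 (edgeR adjusted p = 0.00556 and 0.0206). The MHC class I median was -3.095 without KPCA.C replicate 1 and -1.047 without KPCA.C replicate 2, and H2-K1 stood at 1204 and 231 CPM in these libraries. Nlrc5 lost its call without KPCA replicates 1 or 2 (edgeR adjusted p = 0.0554 and 0.0706). Cytosolic DNA sensing genes fell in 3 of 8 cases (median -0.71, camera adjusted p = 0.00723; adjusted p = 0.495 with an estimated correlation). The 3 were Ccl5, Cxcl10 and Ifi204, of which the first 2 encode chemokines rather than sensors. This list had a camera adjusted p of 0.0621 without KPCA.C replicate 2. Each of the 3 genes lost its call without KPCA replicates 2 or 3 or KPCA.C replicate 2, and Cxcl10 and Ifi204 also without KPCA replicate 1 (edgeR adjusted p between 0.0506 and 0.146).

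Of the 16 epithelial and fallopian tube genes 9 fell, 11 over the list alone (median -3.11, camera adjusted p = 4e-12; adjusted p = 0.187 with an estimated correlation). Cldn7 (log2 -7.35) and Elf3 (log2 -6.56) were among them, and Esrp1 had 3 counts against 866, a ratio of 193 (95% counting interval 65.7 to 936). Among the genes with the largest decreases, Alox12e, Fcgbp, the signalling gene Wnt7a, Grb7, the claudin gene Cldn6 and Cxcl17 had 0 counts in KPCA.C. They were at least 199-fold, 193-fold, 186-fold, 141-fold, 119-fold and 46.1-fold lower. Tspan1, Fut2, the surfactant gene Sftpd and Wfdc18 had 1 count each, with ratios of 862 (95% counting interval 155 to 34100), 564 (101 to 22300), 465 (83.1 to 18400) and 433 (77.5 to 17100). Fibroblast genes fell in 3 of 14 cases, Pdgfra (log2 -2.05), Dpt (-3.73) and Lum (-2.39). The list median was -0.26 (camera adjusted p = 0.0137; adjusted p = 0.649 with an estimated correlation). This call was lost without KPCA replicate 2 (limma camera adjusted p = 0.0958) or KPCA.C replicate 2 (0.381), with medians of -0.054 and -0.031, and the median was -1.592 without KPCA.C replicate 1. Without KPCA.C replicate 2 the edgeR adjusted p was 0.056 for Pdgfra, 0.0956 for Lum and 0.082 for Sftpd. Lum lost its call without KPCA replicates 1 or 2 as well (edgeR adjusted p = 0.0506 and 0.0691), and Sftpd without KPCA replicates 2 or 3 (0.0567 and 0.0626).

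MYC target genes were higher in KPCA.C. Of 20 MYC target and ribosome biogenesis genes 10 rose, 17 over the list alone (median 1.06, camera adjusted p = 1.48e-10; adjusted p = 0.203 with an estimated correlation). Ncl (ENSMUSG00000026234), which encodes the nucleolar protein nucleolin, had 1430 CPM ± 152 (SD, n = 2) against 537 ± 90.9 (SD, n = 3) (edgeR adjusted p = 0.0152), and Npm1 (log2 1.45, edgeR adjusted p = 0.0176) and Dkc1 (log2 1.54, edgeR adjusted p = 0.00937) rose too. RAS-ERK output genes had 3 members up and 1 down of 19 (median 0.5, camera adjusted p = 0.0049; adjusted p = 0.286 with an estimated correlation). Ereg and Areg, which encode ligands of the EGF receptor, rose (log2 5.94 and 2.57, edgeR adjusted p = 0.0113 and 0.0129), as did the phosphatase gene Dusp5 (log2 1.83). Spry1, a feedback inhibitor gene, fell (log2 -1.67, edgeR adjusted p = 0.0176). Without KPCA.C replicate 2 the list had a median of 0.243 and a camera adjusted p of 0.0578, and without KPCA.C replicate 1 the median was 0.961. Proliferation genes had 1 of 26 members up, the nucleotide synthesis gene Rrm2 (log2 1.44, edgeR adjusted p = 0.034), and 0 over the list alone (median 0.39, camera adjusted p = 0.0108; adjusted p = 0.721 with an estimated correlation). That call was lost without KPCA replicate 3 (limma camera adjusted p = 0.176) or KPCA.C replicate 1 (0.436), with medians of 0.232 and 0.127, and the median was 0.614 without KPCA.C replicate 2. Among the largest increases, Sox2 (ENSMUSG00000074637), a stem cell transcription factor gene, had 719 counts in KPCA.C and 0 in KPCA and was at least 359-fold higher. Nefl, a neurofilament gene, had 2146 counts against 3, a ratio of 1070 (95% counting interval 366 to 5200). The log2 fold change of Nefl ranged from 7.529 to 10.94 when 1 library was left out. Fam84a (log2 6.04, SE 0.51), the cadherin gene Cdh15 (8.70), Prokr2 (6.66), Peg3 (7.52) and the muscle acetylcholine receptor gene Chrna1 (6.34) also rose, with edgeR adjusted p between 0.00162 and 0.0269. With 1 library left out, Cdh15 ranged from 6.301 to 9.75 and Prokr2 from 4.452 to 7.5 on the log2 scale. Syt7, the ion channel gene Hcn1 and Khdrbs2 had 2, 3 and 2 counts in KPCA, with ratios of 204 (95% counting interval 55.9 to 1690), 96.9 (32.7 to 474) and 71.2 (19.2 to 596). Without KPCA.C replicate 2 Peg3 was at 2.33 and Chrna1 at 0.72 on the log2 scale and neither was called, nor was either without KPCA replicates 1, 2 or 3 (edgeR adjusted p between 0.0839 and 0.101). Rrm2 and Dusp5 lost their calls without any 1 of the KPCA replicates or KPCA.C replicate 2 (edgeR adjusted p between 0.0809 and 0.231). Ncl, Npm1 and Spry1 lost theirs without KPCA replicate 2 or KPCA.C replicate 2, Npm1 also without KPCA replicate 3, Dkc1 without KPCA replicate 2, and Areg without KPCA replicates 1 or 2 (edgeR adjusted p between 0.0506 and 0.079).

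By edgeR 1477 of 15838 genes passed in KPCA.C versus KPCA, 482 higher and 995 lower, and 1456 of these changed at least 2-fold. DESeq2 called 2634, 1018 higher and 1616 lower. Camera called 16 of 35 lists with the preset correlation and 0 with an estimated one. Without KPCA replicates 1, 2 or 3 in turn edgeR called 594, 512 and 739 genes, and without KPCA.C replicates 1 or 2 it called 2321 and 595. Of the 79 named called genes 39 stayed called in all 5 of these fits, Epcam, Csf1r, H2-Eb1, Gbp4, Cxcl9, Cd274, Sox2 and Nefl among them. Of the 16 lists 9 stayed called in all 5.

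**Figure D4:**
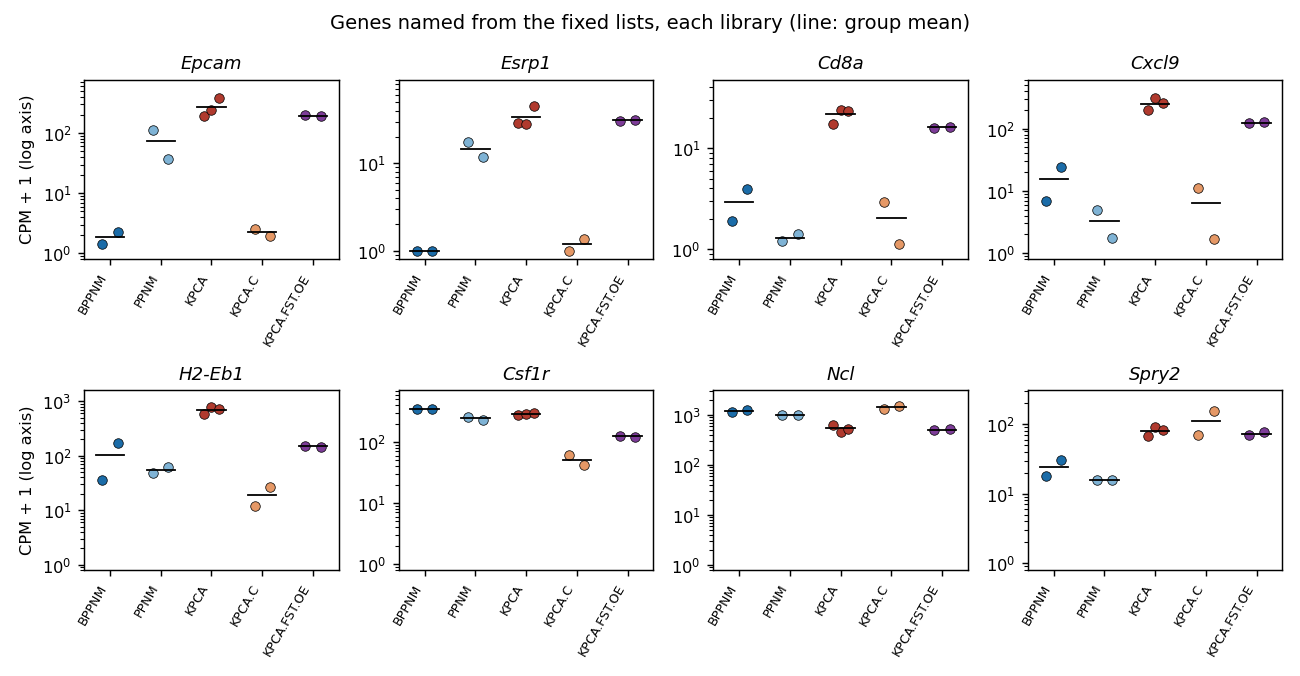
CPM plus 1, on a log axis, of 8 genes named from the lists, in each library by line, with points for libraries and a line at the group mean. Epcam and Esrp1 are low in BPPNM and KPCA.C (Epcam means 0.849 and 1.27 CPM against 73.2 in PPNM and 273 in KPCA), and Cd8a, Cxcl9 and H2-Eb1 are highest in KPCA (means 20.5, 251 and 706 CPM).

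KPCA.FST.OE versus KPCA compared clone B tumors of the line given as overexpressing FST with clone B tumors without it, and higher Fst was not seen in these counts (log2 -0.27). The macrophage and monocyte list was lower in the KPCA.FST.OE sample, with a median log2 fold change of -1.37 (camera adjusted p = 6.95e-09; adjusted p = 0.706 with an estimated correlation), although edgeR called 0 of its 19 members. Lyz2, which encodes lysozyme, had 463 CPM against 1500 ± 332 (SD, n = 3) in KPCA, a log2 fold change of -1.69 (SE 0.6, edgeR adjusted p = 0.41), and the complement gene C1qa had a log2 fold change of -1.98 (edgeR adjusted p = 0.393). The T cell list did not pass (median log2 -0.62, camera adjusted p = 0.184), with 0 of 18 members called by edgeR or DESeq2 or at an unadjusted p under 0.05. Cd8a was at 14.9 CPM against 20.5 ± 3.49 (SD, n = 3; edgeR adjusted p = 0.879) and Lck at a log2 fold change of -0.59 (edgeR adjusted p = 0.714). Activin and TGF-beta signalling genes, chosen because follistatin binds activin, had a median of -0.24 (limma camera adjusted p = 0.324). Of the 24 members 0 were called by edgeR or DESeq2, and 1 had an unadjusted p under 0.05. The matrix genes Ccn2 and Ltbp1 were at 0.49 and 0.51 on the log2 scale (edgeR adjusted p = 0.819 and 0.703).

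Of the macrophage and monocyte genes 8 fell when adjusted over the list alone, 10 had an unadjusted p under 0.05, and DESeq2 called 4. Lower medians were also found for proliferation (-0.75, camera adjusted p = 1.94e-08), fibroblast (-1.18, 3.17e-06) and MHC class II presentation genes (-1.83, 2.7e-05), each with adjusted p = 0.706 with an estimated correlation. In these 3 lists edgeR called 0 members, 8, 4 and 4 members had an unadjusted p under 0.05, and DESeq2 called 0, 3 and 1. Interferon response (-0.91, 0.00144), pancreatic acinar (-5.22, or -3.11 with genes at 0 to 3 counts at their bound, 0.00255) and cholesterol synthesis (-0.65, 0.00532) lists were lower as well. So were the MHC class I presentation (-0.67, 0.0322) and immediate early gene (-0.66, 0.0322) lists. In these 5 lists edgeR and DESeq2 called 0 members, 0, 1, 2, 0 and 1 had an unadjusted p under 0.05, and adjusted p = 0.822 with an estimated correlation. Top2a and Mki67, markers of dividing cells, were at -0.74 and -0.71, and the collagen genes Col1a1 and Col3a1 at -0.88 and -1.01 on the log2 scale (edgeR adjusted p between 0.597 and 0.66). The pancreatic and cholesterol calls were lost without KPCA replicate 1 (limma camera adjusted p = 0.0867 and 0.053). The MHC class I call was lost without KPCA replicates 2 or 3 (0.0599 and 0.0515), and the immediate early call without KPCA replicate 3 or KPCA.FST.OE replicate 2 (0.0805 and 0.053). Without KPCA replicate 1 the pancreatic median was -2.548, and without KPCA replicate 3 the immediate early median was -0.398. The comparison itself runs across the split of the libraries and between days 44 and 45 and day 35. In PPNM against KPCA, across the same split, 7 of the 9 lower lists were lower too: macrophage (-0.87), MHC class II (-3.55), MHC class I (-3.69), interferon (-2.33), pancreatic (-3.13), cholesterol (-0.46) and immediate early (-0.41), while the proliferation median was 0 and the fibroblast median 0.81. Both comparisons use the same KPCA libraries, so a shared direction is not independent and can arise without an effect of the library set. BPPNM and PPNM against KPCA.C shares no library with KPCA.FST.OE versus KPCA. There the proliferation median was -0.31 (quartiles -0.72 to -0.17), and macrophage, fibroblast and MHC class II medians were higher, at 1.62, 1.14 and 2. The other 5 medians there were lower: interferon -0.23, MHC class I -0.52, pancreatic -2.64, cholesterol -1.01 and immediate early -0.67. In KPCA.FST.OE versus PPNM, within a set, the fibroblast median was -1.93 (limma camera adjusted p = 2.21e-05; adjusted p = 0.396 with an estimated correlation) and the proliferation median -0.79 (1.01e-05; 0.422). The MHC class II, MHC class I and interferon medians were higher there, at 1.4, 2.4 and 1.45. That comparison rests on the same summed KPCA.FST.OE sample, so a shared direction is not independent. The macrophage (-0.97), pancreatic (-2.34), cholesterol (-0.23) and immediate early (-0.18) lists did not pass there (limma camera adjusted p between 0.0683 and 0.506).

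Gene by gene, edgeR called 18 of 15838, 16 higher and 2 lower in KPCA.FST.OE, while 1609 had an unadjusted p under 0.05 and DESeq2 called 273. Most of the 18 were higher, but this direction did not hold in wider sets of calls: 101 were higher and 172 lower by DESeq2, and 192 and 218 by edgeR without a filter on low counts. Of the 18 genes 15 were not nuclear protein-coding genes. The others were the small ubiquitin-like modifier gene Sumo2 (log2 5.02, SE 0.5, edgeR adjusted p = 0.00667), the translocon gene Sec61g (log2 3.98, SE 0.4, edgeR adjusted p = 0.00667) and the ATP synthase gene Atp5l (log2 3.24, SE 0.4, edgeR adjusted p = 0.0222). The mitochondrial gene mt-Co3 had 225 counts against 0 and was at least 90.1-fold higher. It was the 1 of 13 mitochondrially encoded genes called, while 6 rose over the list alone (median 1.41, mean 4.39, camera adjusted p = 2.41e-15; adjusted p = 0.706 with an estimated correlation). These features followed the split of the libraries, in which mt-Co3 had 0 counts in each KPCA and KPCA.C library. The KPCA.FST.OE group counted as 1 sample, and with its libraries as 2 samples 468 genes were called, 233 higher and 235 lower, and with the replicate number as a block as well 15 and 19. Without KPCA replicates 1, 2 or 3 in turn 6, 3 and 5 genes were called, and each of Sumo2, Sec61g, Atp5l and mt-Co3 lost its call without replicate 2 (edgeR adjusted p = 0.0643, 0.0674, 0.149 and 0.12).

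Whether KPCA.FST.OE tumors differed from clone B tumors the way clone C tumors do was read from the log2 changes of both groups from KPCA. These had a Pearson correlation of 0.174 across 15838 genes, which are not independent replicates. Both changes share the 3 KPCA libraries, which alone give a correlation. In 20 simulations with no change in either group it averaged 0.321 (range 0.29 to 0.353). Changes in 1 group alone lower a correlation, and edgeR called 1477 genes in KPCA.C versus KPCA. The observed correlation therefore cannot be read against that range. The covariance was 0.318, above its simulated range of 0.178 to 0.229. By edgeR 1 gene was called in the same direction in both comparisons, lower in each, against 0.126 lower if the lists were independent. The shared KPCA libraries make the lists dependent, so 0.126 is not a value for no shared change. The simulations, with both groups unchanged, gave 0 genes lower in both. With separate controls, 1 KPCA library for one change and the other 2 for the other, a version chosen after the data were seen, the 6 possible divisions gave correlations of 0.024 to 0.12 (mean 0.08). In the simulations that mean ranged from -0.028 to 0.021. The simulated genes vary independently, which real genes do not, so these ranges are narrower than chance would give, and a shared change was not shown.

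KPCA versus PPNM asked how tumors of the KRAS, Ccne1 and Akt2 line differed from those of the Pten, Nf1 and Myc line. T cell, antigen presentation and interferon genes were higher in KPCA: 13 of 18 T cell genes, 11 of 14 MHC class I presentation genes, all 7 MHC class II presentation genes and 12 of 26 interferon response genes rose. Cd8a had 20.5 CPM ± 3.49 (SD, n = 3) in KPCA and 0.307 ± 0.148 (SD, n = 2) in PPNM, a log2 fold change of 5.98 (SE 1, edgeR adjusted p = 0.0104). H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347), a classical MHC class I heavy chain gene, had 2380 CPM ± 508 (SD, n = 3) against 83.2 ± 2.21 (SD, n = 2), a log2 fold change of 4.84 (SE 0.69, edgeR adjusted p = 0.00699). Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) had 251 CPM ± 52.9 (SD, n = 3) against 2.34 ± 2.26 (SD, n = 2), a log2 fold change of 6.77 (SE 1.18, edgeR adjusted p = 0.012). Dusp6 (ENSMUSG00000019960), a phosphatase induced by ERK signalling, had 237 CPM ± 11.3 (SD, n = 3) against 83.6 ± 2.97 (SD, n = 2), a log2 fold change of 1.5 (SE 0.24, edgeR adjusted p = 0.00929). Without PPNM replicate 1 the edgeR adjusted p values of Cd8a, H2-K1, Cxcl9 and Dusp6 were 0.0916, 0.0625, 0.0607 and 0.0593, and without PPNM replicate 2 those of Cd8a and Cxcl9 were 0.0541 and 0.0612.

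All 18 T cell genes rose over the list alone (median 4.13, or 4.16 with genes at 0 to 3 counts at their bound, camera adjusted p = 5.15e-16; adjusted p = 0.215 with an estimated correlation). They included Lck (log2 5.14, SE 0.59, edgeR adjusted p = 0.00384) and Cd3e, with 219 counts against 2 (ratio 97.0, 95% counting interval 26.5 to 806). Of 14 cytotoxic and NK cell genes 11 rose, 13 over the list alone (median 4.66, or 4.6 at the bound, camera adjusted p = 1.06e-13; adjusted p = 0.215 with an estimated correlation). Prf1, which encodes perforin, had 430 counts against 3 (ratio 127, 95% counting interval 43.2 to 618), and Ifng was at least 20.1-fold higher. The regulatory T cell and checkpoint list had 7 of 14 members up, 10 over the list alone (median 2.87, camera adjusted p = 4.33e-07; adjusted p = 0.256 with an estimated correlation). Cd274 had 51.1 CPM ± 3.42 (SD, n = 3) against 7.39 ± 0.56 (SD, n = 2; edgeR adjusted p = 0.00419), and Ctla4 was at least 11.8-fold higher. Plasma cell genes rose in 6 of 10 cases, 9 over the list alone (median 8.10, or 7.75 at the bound, camera adjusted p = 4.33e-07; adjusted p = 0.288 with an estimated correlation). Igha had 428 CPM ± 521 (SD, n = 3) against 1.09 ± 0.547 (SD, n = 2; edgeR adjusted p = 0.0136), and Ighg2b was at least 221-fold higher. The same test in KPCA.FST.OE versus PPNM, which lie in the same library set, gave medians of 3.57 for T cells (limma camera adjusted p = 2.82e-14), 4.47 for cytotoxic cells (2.85e-12), 2.39 for regulatory T cells and checkpoints (3.01e-05) and 6.20 for plasma cells (3.42e-08). With an estimated correlation these adjusted p values were 0.186, 0.186, 0.339 and 0.339, and the comparison rests on 1 summed sample and the same PPNM libraries. Without PPNM replicate 1 the edgeR adjusted p was 0.0635 for Cd3e. Ifng, Ctla4, Igha and Ighg2b lost their calls without PPNM replicates 1 or 2, Ifng also without KPCA replicate 2 and Ctla4 without any 1 of the KPCA replicates (edgeR adjusted p between 0.0511 and 0.124).

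The MHC class I list had a median of 3.69 and 11 members up over the list alone (camera adjusted p = 5.15e-16), and the MHC class II list a median of 3.55 (camera adjusted p = 6.35e-11), both with adjusted p = 0.256 with an estimated correlation. The nonclassical class I gene H2-Q7 (log2 5.78), Nlrc5 (3.86), Tap2 (2.73), Ciita (3.86) and H2-Eb1 (3.70) rose, with edgeR adjusted p between 0.00419 and 0.0136. Interferon response genes had a median of 2.33 and 23 up over the list alone (camera adjusted p = 2.02e-15; adjusted p = 0.288 with an estimated correlation). Gbp4 had a log2 fold change of 5.42 and Cxcl10 one of 4.41 (edgeR adjusted p = 0.00166 and 0.0139). Ido1, a tryptophan-degrading enzyme gene, was at least 52.6-fold higher. RAS-ERK output genes rose in 8 of 19 cases, 11 over the list alone (median 1.32, camera adjusted p = 5.73e-06; adjusted p = 0.215 with an estimated correlation). Among them were Spry2 (log2 2.42), Spry4 (1.97) and Spry1 (1.69), feedback inhibitors of the pathway. MYC target and ribosome biogenesis genes fell in 6 of 20 cases, 11 over the list alone (median -0.88, camera adjusted p = 4.33e-07; adjusted p = 0.263 with an estimated correlation). Npm1 had a log2 fold change of -1.97 (SE 0.29, edgeR adjusted p = 0.0075) and the fibrillarin gene Fbl one of -1.56 (edgeR adjusted p = 0.00931). In KPCA.FST.OE versus PPNM the medians were 2.40 for MHC class I (limma camera adjusted p = 1.95e-12), 1.40 for MHC class II (0.000541), 1.45 for interferon response (3.42e-08), 1.51 for RAS-ERK output (7.83e-08) and -0.96 for MYC targets (1.06e-06). With an estimated correlation these adjusted p values were 0.339, 0.422, 0.462, 0.186 and 0.339. H2-Eb1, Cxcl10, Ido1, Spry2, Spry4 and Spry1 lost their calls without PPNM replicates 1 or 2, Ido1 and Spry1 also without KPCA replicate 2, and Ciita and Fbl without PPNM replicate 1 (edgeR adjusted p between 0.0511 and 0.112).

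Epithelial genes rose in 3 of 16 cases, Sox17 (log2 2.64), Krt7 (2.78) and Krt18 (1.64), and each lost its call without any 1 of the 5 libraries (edgeR adjusted p between 0.0511 and 0.175). The list median was 1.53 (camera adjusted p = 0.000154; adjusted p = 0.346 with an estimated correlation), and 1.27 in KPCA.FST.OE versus PPNM (limma camera adjusted p = 0.000202; adjusted p = 0.422 with an estimated correlation). Cytosolic DNA sensing genes rose in 4 of 8 cases, Ifi204 (log2 1.58) and Tmem173 (1.22), which encodes the adaptor STING, and the chemokine genes Ccl5 and Cxcl10. Ifi204 and Tmem173 lost their calls without any 1 of the 5 libraries (edgeR adjusted p between 0.0558 and 0.16), and Ccl5 and Cxcl10 without PPNM replicates 1 or 2 (between 0.064 and 0.093). The list median was 0.95 (camera adjusted p = 0.00238; adjusted p = 0.384 with an estimated correlation), and 0.65 in KPCA.FST.OE versus PPNM (limma camera adjusted p = 0.0361; adjusted p = 0.571 with an estimated correlation). In 5 other lists few members rose. They were 1 of 9 dendritic cell genes, Irf8 (log2 1.89), 2 of 19 macrophage genes, Ly6c2 (5.25) and Arg1 (2.24), and 1 of 12 neutrophil genes, Il1r2 (2.47). Wt1 (log2 4.78) rose among 10 mesothelial genes and Ighm (5.80) among 5 B cell genes. Of these only Irf8 stayed called in all 5 fits with 1 library left out: Arg1, Il1r2 and Ighm lost their calls in each, Wt1 without PPNM replicate 2 or any 1 of the KPCA replicates, and Ly6c2 without PPNM replicates 1 or 2 (edgeR adjusted p between 0.0514 and 0.19). The list medians were 1.89, 0.87, 1.82, 1.82 and 1.17, with limma camera adjusted p values of 0.00896, 0.00896, 0.00238, 0.0185 and 0.036. With an estimated correlation the adjusted p values of these lists were 0.288, 0.536, 0.384, 0.444 and 0.384. In KPCA.FST.OE versus PPNM the macrophage median had the opposite sign, at -0.97 (limma camera adjusted p = 0.0683). The dendritic and B cell lists did not pass there (limma camera adjusted p = 0.212 and 0.144), and the neutrophil and mesothelial lists did (3.01e-05 and 0.00322; adjusted p = 0.339 and 0.422 with an estimated correlation). Without PPNM replicate 1 the neutrophil and B cell medians in KPCA versus PPNM were 3.467 and 2.002, and without PPNM replicate 2 the neutrophil median was 1.149. Without PPNM replicate 2 the limma camera adjusted p values were 0.255 for B cells, 0.142 for macrophages, 0.195 for neutrophils and 0.143 for mesothelium, and without KPCA replicate 2 that of B cells was 0.0578.

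By edgeR 1629 of 15838 genes passed in KPCA versus PPNM, 785 higher and 844 lower, and DESeq2 called 2767, 1534 higher and 1233 lower. By camera 18 of 35 lists passed with the preset correlation against 0 with an estimated one. Besides immunoglobulin genes, the largest increases were in Frzb, a Wnt antagonist gene, Nlgn1 and Rps6ka6, at least 104-fold, 75.3-fold and 65.9-fold higher, and in Alox12e, with 895 counts against 2 (ratio 396, 95% counting interval 109 to 3280). Nlgn1 lost its call without any 1 of the 5 libraries (edgeR adjusted p between 0.0531 and 0.111), and the other 3 genes kept theirs. The largest decreases in nuclear genes included Car3 (log2 -7.23), the Nogo receptor gene Rtn4r, with 2 counts against 203 (ratio 115, 95% counting interval 31.3 to 952), the developmental regulator genes Tbx18 (-5.83) and Eya4 (-5.70, SE 0.63) and Tnfrsf25 (-5.63), with edgeR adjusted p between 0.00342 and 0.0139. Car3 was at -3.917 without PPNM replicate 2 and lost its call there and without any 1 of the KPCA replicates (edgeR adjusted p between 0.0524 and 0.0801), and the others kept theirs without any 1 of the 5 libraries. Mitochondrially encoded genes fell in 8 of 13 cases (median -2.06, camera adjusted p = 6.09e-14; adjusted p = 0.258 with an estimated correlation), and within the library set the median was -0.79 (camera adjusted p = 0.0773). Without PPNM replicate 1 the median in KPCA versus PPNM was -1.3. The mt-Co3, mt-Co2 and mt-Atp6 genes, Sumo2 (-5.63) and the ribosomal protein gene Rpl24 (-5.85) were among the largest decreases. The 3 mitochondrial genes had 0 counts in every KPCA and KPCA.C library and so followed the split of the libraries. Sumo2 was also called higher in KPCA.FST.OE than in KPCA, across the same split. For these genes the line and the library set cannot be told apart in KPCA versus PPNM. Of the 1277 nuclear protein-coding genes called, 1238 had the same direction in KPCA.FST.OE versus PPNM and 219 were also called there, with a median ratio of the log2 changes of 0.81. Of the 352 other features called, 325 had the same direction and 12 were also called, with a ratio of 0.39. That comparison used the same PPNM libraries, so the shared direction is not independent. Without PPNM replicates 1 or 2 edgeR called 198 and 597 genes, and without KPCA replicates 1, 2 or 3 it called 515, 400 and 657. Of the 67 named called genes 22 stayed called in all 5 fits.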

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

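Of the choices named here, the summing of KPCA.FST.OE, which made its planned form as 2 samples an alternative, nuclear protein-coding genes only and separate controls were chosen after the data were seen. In the order BPPNM versus PPNM, KPCA.C versus KPCA, KPCA.FST.OE versus KPCA and KPCA versus PPNM, edgeR called 96, 1477, 18 and 1629 genes. Without a filter on low counts it called 994, 2786, 410 and 3050, of which 96, 1389, 18 and 1545 were shared with the reported calls in the same direction. With KPCA.FST.OE as 2 samples, the planned fit, it called 237, 2412, 468 and 2687, which kept all of the reported calls, and DESeq2 called 529, 2634, 273 and 2767, which kept 95, 1457, 18 and 1586. With the replicate number as a block, which was run with KPCA.FST.OE as 2 samples, 34 genes were called in KPCA.FST.OE versus KPCA, and with the compared groups alone 894 in KPCA.C versus KPCA and 41 in KPCA.FST.OE versus KPCA. Among nuclear protein-coding genes only, 2 were called in KPCA.FST.OE versus KPCA, where the restriction itself removes 15 of the 18 genes. RLE factors gave 95, 1476, 16 and 1651. Leaving out 1 library at a time gave 3 to 111, 512 to 2321, 3 to 16 and 198 to 657 genes, and 8 to 18, 14 to 21, 8 to 10 and 15 to 20 lists. These fits have fewer samples, and where an arm keeps 1 library, that library is assumed to vary like the other groups. With an estimated correlation 0, 0, 0 and 0 lists passed, against 13, 16, 10 and 18 with the preset one. The correlation of changes of 0.174 moved to 0.323 without a filter, to 0.242 with the block and to 0.08 with separate KPCA libraries as controls, and ranged from 0.157 to 0.239 when 1 library was left out. Mylpf in KPCA.C versus KPCA, at 6.03 on the log2 scale, was at -0.823 without KPCA.C replicate 2 and ranged up to 7.028 when other libraries were left out, and the skeletal muscle median was 0 without that library and ranged up to 7.989. Except where fewer samples or genes explain a change, the cause was not tested. Recovery in the simulations sets the limit of depth and sample number: few 2-fold changes could be called in any comparison.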

Other observations

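The list tests by camera were planned, and of the 11 tests of explanations the search for near-identical copies was chosen before its result was seen. The other 10, and the tests by chromosome, were chosen after the results were seen.

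Several lists did not pass in any of the 4 comparisons. In the order BPPNM versus PPNM, KPCA.C versus KPCA, KPCA.FST.OE versus KPCA and KPCA versus PPNM, the p53 target list had medians of -0.21, 0.14, -0.17 and -0.12, and the limma camera adjusted p values were 0.168, 0.898, 0.719 and 0.552. Homologous recombination repair genes had medians of 0.14, 0.32, -0.4 and 0.08 (0.499, 0.123, 0.202 and 0.913), and mesenchymal transition genes of -0.23, 0.22, -0.41 and -0.55 (0.827, 0.593, 0.198 and 0.489). For endothelial cells the medians were 0.64, 0.3, 0.35 and 0.23 (0.0702, 0.891, 0.644 and 0.438), and for adipocytes -0.96, 1.15, 0.2 (0.14 with genes at 0 to 3 counts at their bound) and -1.83 (0.632, 0.671, 0.644 and 0.208). Mast cell medians were 3.47 (3.19 with genes at 0 to 3 counts at their bound), 1.98, -0.24 and 1.8 (1.85 at the bound), with limma camera adjusted p values of 0.1, 0.642, 0.9 and 0.349, and red blood cell medians were 0.18, -1.2, 0.5 and -0.59 (0.824, 0.217, 0.651 and 0.388). Activin and TGF-beta signalling genes had medians of -0.25, -0.11, -0.24 and 0.56 (0.118, 0.32, 0.324 and 0.0657). In KPCA.C versus KPCA 3 of the 24 activin and TGF-beta genes fell by edgeR, the inhibitory Smad gene Smad6 (log2 -2.67, adjusted p = 0.0113), the ligand gene Tgfb3 (-1.56, 0.0158) and the binding protein gene Ltbp2 (-2.41, 0.0303), and in KPCA versus PPNM the activin receptor gene Acvr1b rose (1.31, 0.0198). Smad6 lost its call without KPCA.C replicate 2, Tgfb3 also without KPCA replicate 2, Ltbp2 without any 1 of the 5 libraries, and Acvr1b without KPCA replicates 1 or 2 or PPNM replicates 1 or 2 (edgeR adjusted p between 0.0502 and 0.141).

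Markers of neighbouring tissue varied between single libraries. Pancreatic acinar genes were higher in BPPNM than in PPNM (median 3.13, or 3.22 with genes at 0 to 3 counts at their bound, limma camera adjusted p = 0.000544; adjusted p = 0.669 with an estimated correlation), without a member called by edgeR or DESeq2 and with 1 at an unadjusted p under 0.05. That call was lost without BPPNM replicate 2 (median 1.28, limma camera adjusted p = 0.0578) or PPNM replicate 2 (0.1), and the median was 5.599 without PPNM replicate 1. Skeletal muscle genes were lower in BPPNM than in PPNM (median -4.54, or -4.78 at the bound, limma camera adjusted p = 0.00175; adjusted p = 0.669 with an estimated correlation) and in KPCA than in PPNM (median -4.99, or -5.14 at the bound, limma camera adjusted p = 0.0266; adjusted p = 0.652 with an estimated correlation). Without PPNM replicate 2 these medians were -0.346 and -0.29 (limma camera adjusted p = 0.36 and 0.57). Plasma cell genes were lower in KPCA.C than in KPCA (median -2.89, limma camera adjusted p = 0.00852; adjusted p = 0.683 with an estimated correlation), with 1 of 10 called, Igha, and the call was lost without KPCA.C replicate 2 (limma camera adjusted p = 0.301). The plasma cell median was -1.513 without KPCA replicate 2 and -4.997 without KPCA.C replicate 1. Igha lost its call without KPCA replicate 2 or KPCA.C replicates 1 or 2 (edgeR adjusted p = 0.0537, 0.074 and 0.118).

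The few genes called in KPCA.FST.OE versus KPCA, and the lower stromal lists there, follow a comparison across the library sets. Of the 18 called genes 13 (72.2%, exact 95% interval 46.5% to 90.3%) had a near-identical transcript of another gene, against 15 of 200 random genes (7.5%, 4.3% to 12.1%). The random genes were not matched on biotype, and 15 of the 18 called genes were not nuclear protein-coding genes. The excess can therefore reflect the kind of feature called, and it does not show that copies led to the calls. Sumo2, Sec61g and Atp5l, the 3 nuclear protein-coding genes, had none by this measure over the longest transcript, so copies do not account for them as far as it shows. In BPPNM and PPNM against KPCA.C 17 of the 18 went the same way, but 7 of them are among the features by which the split was found, and their direction was fixed by that choice. Of the 11 others 10 went the same way (two-sided exact binomial p = 0.0117 against an even split, as if genes were independent). Among all other genes 56.1% did, a share that this p was not set against. A difference in how reads of these genes were obtained or counted in the library sets could give this pattern. For the stromal lists, a lower share of all non-tumor cells would lower the endothelial list too. Its median was 0.35 (quartiles -0.01 to 0.5) where the macrophage median was -1.37 (-1.89 to -1.02). This argues against such a lower share for the summed KPCA.FST.OE sample only. The quartiles are over genes of that sample, which are not independent, and do not measure the spread between tumors. The same macrophage list had a median of 1.62 (0.56 to 2.63) in BPPNM and PPNM against KPCA.C. It was -0.87 (-1.23 to -0.13) in PPNM against KPCA, which shares the KPCA libraries with KPCA.FST.OE versus KPCA. These 2 comparisons across the sets thus differ in direction. The fibroblast list, at -1.18 (-1.59 to -0.63), had a median of 1.14 (-0.25 to 2.33) and of 0.81 (-1.05 to 1.46) in these comparisons, against the direction a shared effect of the set would have, but with quartiles on both sides of 0. Within the set, in KPCA.FST.OE versus PPNM, it was -1.93 (limma camera adjusted p = 2.21e-05; adjusted p = 0.396 with an estimated correlation). KPCA.FST.OE versus PPNM uses the same summed KPCA.FST.OE sample, so this value is not independent of the one in KPCA.FST.OE versus KPCA. For the macrophage and fibroblast lists an effect of FST, the library set and the later day cannot be told apart, because each differs between the same samples and the line differs too in the other comparisons.

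Skeletal muscle genes rose in 3 of 7 cases in KPCA.C versus KPCA (median 7.00, or 6.03 at the bound, limma camera adjusted p = 0.012; adjusted p = 0.683 with an estimated correlation), all through KPCA.C replicate 2, without which the median was 0 and the adjusted p 0.936. In that library embryonic and neonatal myosin heavy chains stood at 286 CPM and adult fast ones at 12.3 CPM, a ratio of 23.2, against 0.103 (3.64 and 35.4 CPM) in PPNM replicate 2, which argues against adult skeletal muscle taken with the tumor. The embryonic markers Myh3, Myog, Myod1 and Chrng, chosen after the list result was seen, stood at 282, 158, 95 and 148 CPM there and at no more than 0.222 CPM in KPCA.C replicate 1. The CPM of these markers and of the myosin heavy chains are per library total, without the TMM factors. A tumor of another of these lines under the label was argued against by Akt2, at 1250 CPM beside 1293 CPM in KPCA.C replicate 1 and at most 281 CPM in any library outside KPCA.C. Muscle-like differentiation of the tumor or regenerating host muscle may account for these genes, and neither was tested.

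Epithelial genes were lower in BPPNM versus PPNM and in KPCA.C versus KPCA, comparisons that share no library. Of the 84 genes lower in the first, 57 were also lower in the other, against 5.28 for independent lists (Fisher's exact test, the one-sided hypergeometric p = 9.91e-49, over genes that are not independent), and 51 of them lay outside the epithelial list, Ocln, Dsp and Tmprss2 among them. The engineered genes did not fall with the epithelial genes. Akt2 was higher by 2.37 (SE 0.26) in KPCA.C where the epithelial median was -3.11. Myc was at 0.64 (SE 0.48) in BPPNM where the epithelial median was -3.55. Their level per tumor cell may differ between clones and lines, so these values cannot decide whether the share of tumor cells was lower. One hypothesis is that the tumor cells of both lines may have lost part of an epithelial program. It was not tested here, since RNA of whole tumors does not separate tumor from host cells. Sorted tumor cells, staining of sections or the lines in culture would decide it, and differences between the lines before inoculation, the clone and the day of harvest stay open. Higher in both were 4 genes, Adcy3, Ptgfr, Syce2 and Tbx3, against 0.365 for independent lists.

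Medians of log2 change by chromosome passed a test against 10000 random gene lists for 16, 14, 14 and 15 of 20 chromosomes in the 4 comparisons, 80 tests in all with adjustment over them. Examples are 0.48 for chromosome 14 and -0.43 for chromosome 16 in KPCA versus PPNM, 0.48 for chromosome X in KPCA.C versus KPCA, -0.36 for chromosome 15 in KPCA.FST.OE versus KPCA, and 0.33 for chromosome 14 in BPPNM versus PPNM. Each of these had a p of 0.0001 in the test by random lists, the smallest that number of lists can give. This p treats genes as independent and does not measure the spread between tumors. Called chromosomes 3, 6, 12, 13 and 14 in KPCA.C versus KPCA had their direction in 1 of 2 KPCA.C libraries. So did chromosome 9 in 1 of 2 BPPNM libraries against PPNM, and chromosome 11 in 2 of 3 KPCA libraries against PPNM. The other called chromosomes had it in every library of the first-named group. For KPCA.FST.OE these are the 2 libraries that differed by little more than counting noise, so their shared direction adds no support from replicates. Antisense features held 0.177% to 0.269% of counts in the KPCA and KPCA.C libraries and 0.12% to 0.164% in the others, and processed pseudogenes 0.069% to 0.094% against 0.141% to 0.238%. The ribosomal RNA-like feature Gm42418 held 6.09% to 15.81% against 1.85% to 6.74%.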
